A study of Homo sapiens with 60 samples.

How the data were processed

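Gene expression was measured by RNA sequencing in SW1783 cells (a human astrocytoma line, ATCC HTB-13) kept in Leibovitz's L-15 medium and exposed for 24 h to DMSO or to 70% ethanol extracts of 6 herbs and 2 formulas at 3 doses. Per the labels, the high dose was the concentration that lowers viability by 20% (IC20) where that lay under 500 µg/mL and otherwise 500 µg/mL, and the lower doses were 1/5 and 1/25 of it. Libraries were made with a strand-marking kit (MGIEasy RNA Directional) from RNA with an integrity number above 7 and sequenced as 100 bp paired ends on an MGI instrument. Per the labels of the samples, the vehicle held 0.1% DMSO, while the series text gives 2%. Water extracts and positive controls that the series text names were not analysed here. The deposited values are expected counts per gene, made per the submitters' processing notes with FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a and RSEM 1.3.3 on hg38. The gene annotation, the setting for strand and the role of each program are not given in the sources used here. The file held 60675 genes, 23499 of them without a count in any library, and 9.18% of the values were not whole. They were rounded to whole numbers before testing. Gene positions and types come from GENCODE v29 on GRCh38, which held 57055 of the genes and 99.97% of the counts.

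Samples were grouped by extract and dose from their labels. The 57 libraries of the 22 groups with 2 or 3 libraries entered one fit, and the 3 Banhasasim-tang libraries were described without a test. No vehicle library carries the set number that the extract libraries carry in their names (11 for Coptidis and Zizyphi, 12 for Citri and Cimicifugae, 13 for Bupleuri and Aconiti, 14 for the formulas), so set and treatment cannot be separated in comparisons with the vehicle. High and low doses of an extract share a set. Each dose was compared with the vehicle, each high dose with the low dose, and high-dose Citri with high-dose Cimicifugae, 29 comparisons in all. Genes were kept with filterByExpr at a minimum count of 10, scaled with TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, no block for the replicate number) in R 4.3.3. P-values were adjusted after Benjamini and Hochberg within each comparison, and an adjusted p under 0.05 is called changed. The standard error of a log2 fold change is its size divided by the square root of the test's F value. Standard deviations of CPM use TMM-scaled library sizes.

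Gene lists were written before the data were examined, as were the comparisons, the tests, the main alternatives and the rule for naming genes. The 27 lists cover the AhR, NRF2, ATF4, ER chaperone, cholesterol, fatty acid, LXR, p53, mitotic, DNA replication, NF-kB, interferon, heat shock, metallothionein, hypoxia and glycolysis, MondoA, mitochondrially encoded respiratory chain, extracellular matrix, glucocorticoid, lysosome and MAPK genes and markers of astrocytes, neurons, oligodendrocytes, microglia and leukocytes, endothelium and epithelium. The 26 with at least 3 tested genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation, in 14 comparisons, with Benjamini-Hochberg adjustment within each. A list's median, mean and test differed in sign in 41 of 364 list tests, of which 3 were called, all of the hypoxia and glycolysis list. Counts given over a list alone were adjusted over the list's p-values only. For each extract the rule named the 8 largest rises and 8 largest falls at the high dose among genes with a symbol, an adjusted p under 0.05, a mean of at least 1 CPM and every treated library beyond every vehicle library. It added the 3 called members with the smallest p of up to 5 called lists, the 4 largest changes each way between high and low dose, 5 each way between Citri and Cimicifugae, and 9 genes fixed in advance (CYP1A1, HMOX1, DDIT3, HMGCS1, CDKN1A, TXNIP, MKI67 and IL6, with 1 that is not reported here). Most genes that met the rule but lost their call when 1 library was left out, and some others for length, are not named in the text. For Banhasasim-tang the rule took the 8 largest differences each way in log2 CPM (prior count 2) among genes with a mean of at least 5 CPM whose high and medium libraries lay beyond every vehicle library, and list medians were placed among 10000 random lists matched in 20 expression bins.

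Library totals ran from 11329310 to 30990264 counts. On simulated data with the spread and depth of these libraries, edgeR recovered 57.6% of genes changed 1.5-fold, 90.6% of those changed 2-fold and 99.7% of those changed 4-fold with 3 libraries per group. With 2 against 3 libraries it recovered 48.4%, 87.6% and 99.1%. False calls made up 4.62% and 4.46% of all calls (2.44 to 6.82% and 2.98 to 6.47% over 10 simulations each). The first 3 principal components held 18%, 16.9% and 12.9% of the variance. Correlations between extracts were set against 4 simulations in which only the vehicle libraries were shared. Alternatives were DESeq2 1.42.0, RLE factors, no filter on low counts, a fit of only the groups compared, the replicate number as a block (overall and within the set), leaving out each library in turn, the estimated correlation for lists, Spearman for Pearson correlation, a mean of at least 10 CPM for the correlations between extracts and a prior count of 5 for Banhasasim-tang. Chosen after the data were seen were leaving out the 2 libraries that correlated least with the others, thinning all libraries to the smallest total, removing each library's GC trend in 20 bins and list medians under other scalings. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.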

Results

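RNA abundance per gene was measured by paired-end sequencing in SW1783, an established human astrocytoma line, after 24 h with the vehicle DMSO or with ethanol extracts of 6 medicinal herbs and 2 herbal formulas. Per the labels, the series was made to describe herbal extracts by the expression profiles they cause in cultured cells, so each extract was compared with the vehicle and its high dose with its low dose. The medium, Leibovitz's L-15, supplies galactose where most media supply glucose. High, medium and low doses were 14, 2.8 and 0.56 µg/mL for Coptidis Rhizoma, 210, 42 and 8.4 µg/mL for Bupleuri Radix, and 500, 100 and 20 µg/mL for Zizyphi Fructus, Citri Unshius Pericarpium, Cimicifugae Rhizoma, Aconiti Lateralis Radix Preparata and the formulas Yijung-tang and Banhasasim-tang. There were 3 vehicle libraries, 3 libraries per dose of Citri, Cimicifugae, Bupleuri and Aconiti, 2 per dose of Coptidis, Zizyphi and Yijung-tang and 1 per dose of Banhasasim-tang. Totals ran from 11329310 to 30990264 counts per library, and from 15996157 to 20858002 in the vehicle. Effects are given as log2 fold changes with their standard errors and levels as CPM (counts scaled to library size) with their SD, n being the libraries per group. Nothing in the labels says that replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. Gene lists were tested with camera at a preset correlation between genes, and both p-values are given where a call ended with an estimated correlation.

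At the high dose, the glucose-induced arrestin gene TXNIP rose after Zizyphi, Citri, Cimicifugae and, with no call between doses, Aconiti and fell after Coptidis, Bupleuri and Yijung-tang, and HMOX1, the haem-degrading oxygenase, rose in every extract except Zizyphi and Citri. Whether extracts differed from each other was tested only for Citri against Cimicifugae. Of 17838 genes tested with edgeR, those with an adjusted p under 0.05 against the vehicle numbered 8337 for high-dose Coptidis, 5362 for Aconiti, 2477 for Bupleuri, 1245 for Cimicifugae, 814 for Citri, 770 for Yijung-tang and 277 for Zizyphi. Medium doses gave 704 genes for Cimicifugae, 632 for Coptidis and between 18 and 74 for the other extracts. Low doses gave 139 for Cimicifugae, 5756 for Yijung-tang and between 8 and 44 for the others. These counts moved with a pair of libraries that stood apart from their group mates, replicate 1 of high-dose Aconiti and replicate 1 of low-dose Yijung-tang, which widened the spread that all comparisons share. Without both (the 2 libraries below), an alternative chosen after the data were seen, 11875, 4858, 6987, 6317, 5526, 5421 and 3785 of 18208 genes passed at the high doses in the same order, and 499 for low-dose Yijung-tang to 4740 for low-dose Bupleuri at the low doses.

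The divergent Aconiti library held 11329310 counts, the fewest of all libraries, with 0.144% of them in the mitochondrial ribosomal RNA MT-RNR2, against a vehicle mean of 0.846%. Across genes, its log2 ratio to its group mates had a Spearman correlation of 0.83 with GC content, where 52 other libraries ran from -0.33 to 0.33. In the divergent Yijung-tang library, genes annotated as antisense or lincRNA lay above the replicate of its group (median log2 ratios 0.39 and 0.42) and processed pseudogenes below it (-0.55). Sums of cell type markers went both ways. That Yijung-tang library held 498 CPM of epithelial (replicate 224) and 7 of endothelial markers (29.3). The Aconiti library held 398 of microglia and leukocyte (replicates 219 and 219.9) and 25.6 of endothelial markers (31 and 28.8). Each of these sums compares single libraries, with no test.

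High-dose Coptidis Rhizoma, an extract of the berberine-containing rhizome of Coptis, changed more genes than any other of the 21 replicated extract groups, with 4131 higher and 4206 lower than in the vehicle. NGFR, the low-affinity neurotrophin receptor (ENSG00000064300, chromosome 17, 49495293 to 49515017, plus strand of GRCh38), rose 118-fold (log2 6.88 ± 0.23, 165 ± 13.9 against 1.38 ± 0.245 CPM, n = 2 and 3, edgeR adjusted p = 8.53e-26). The stress cytokine GDF15 (ENSG00000130513, chromosome 19, 18374731 to 18389176, plus strand) rose 112-fold (log2 6.81 ± 0.19, 505 ± 2.34 against 4.51 ± 0.544 CPM, n = 2 and 3, edgeR adjusted p = 5.19e-28). Other large rises were the keratin KRT75 (6.46 ± 0.38), the secreted BMP regulator KCP (5.36 ± 0.30), the hexokinase HKDC1 (5.30 ± 0.18), the lysosomal Rag GTPase RRAGD (5.14 ± 0.29) and the stress transcription factor ATF3 (4.89 ± 0.19). The cell surface glycoprotein CD248 fell 31.4-fold (0.136 ± 0.12 against 4.34 ± 0.647 CPM, n = 2 and 3, edgeR adjusted p = 1.25e-13). The thyroid hormone deiodinase DIO2 fell 23.9-fold (2.59 ± 0.547 against 61.7 ± 3.37 CPM, n = 2 and 3, chromosome 14, 80197527 to 80387757, minus strand, edgeR adjusted p = 1.09e-17). NFE2 (-4.85 ± 0.62), METTL7A (-4.72 ± 0.32) and FAM111B (-4.31 ± 0.52) fell as well. The readthrough gene RPS10-NUDT3 rose by 5.21 ± 1.43, and the antisense gene CD109-AS1 (-5.50 ± 0.69), the serpin SERPINB3 (-4.55 ± 0.41) and MGC27382 (-4.41 ± 0.56) fell. RPS10-NUDT3, CD109-AS1 and SERPINB3 are uncertain, since reads could have been shared with overlapping or near-identical genes and the use of strand in counting is not given in the sources used here.

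The ATF4, ER chaperone and lysosome lists were higher in high-dose Coptidis. Of the ATF4 integrated stress response list, 18 of 20 rose, 1 fell and 1 did not pass, or 19 and 1 over the list alone, with a median of 2.26 (camera adjusted p = 7.71e-46). The proapoptotic transcription factor DDIT3 rose by 4.68 ± 0.20 (645 ± 17.5 against 25.2 ± 0.574 CPM, n = 2 and 3), the pseudokinase TRIB3 by 4.52 ± 0.15 and SESN2 by 3.03 ± 0.11, each with an edgeR adjusted p of at most 4.43e-22. Of the ER chaperone and unfolded protein response list, 14 of 14 rose, 0 fell and 0 did not pass, or 14 and 0 over the list alone (camera adjusted p = 1.27e-14). The main ER chaperone HSPA5 went from 3709 ± 34.9 to 19030 ± 411 CPM (n = 3 and 2, log2 2.36 ± 0.09). HERPUD1 and XBP1 rose by 3.07 ± 0.08 and 1.73 ± 0.09 (edgeR adjusted p of at most 5.54e-20). Of the lysosome and TFEB list, 11 of 14 rose, 1 fell and 2 did not pass, or 12 and 1 over the list alone (camera adjusted p = 2.6e-07). WIPI1 (1.92 ± 0.08), GPNMB (1.51 ± 0.10) and the autophagy receptor SQSTM1 (1.49 ± 0.12) were among its rises. The p53 target list was higher (7 of 16 rose, 1 fell and 8 did not pass, or 7 and 1 over the list alone, camera adjusted p = 1.07e-05). CDKN1A, the cell cycle inhibitor in it, rose by 1.31 ± 0.13. Glucocorticoid targets were also higher (5 of 6 rose, 0 fell and 1 did not pass, or 5 and 0 over the list alone, camera adjusted p = 4.27e-06), as was the MAPK and immediate-early list (8 of 12 rose, 2 fell and 2 did not pass, or 8 and 2 over the list alone, camera adjusted p = 0.000156, but adjusted p = 0.0905 with an estimated correlation without the 2 libraries). IL6 rose by 3.79 ± 0.16 (55 ± 0.204 against 3.95 ± 0.659 CPM, n = 2 and 3, edgeR adjusted p = 2.43e-22) and HMOX1 by 1.55 ± 0.14 (edgeR adjusted p = 1.09e-12). The list of NF-kB cytokines and chemokines that holds IL6 was higher (8 of 13 rose, 2 fell and 3 did not pass, or 8 and 2 over the list alone, camera adjusted p = 0.000543, but adjusted p = 0.0585 without the 2 libraries).

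Cell division genes fell in the same samples. All 15 mitotic G2/M genes fell (15 adjusted over the list alone, median -1.56, camera adjusted p = 3.44e-15), including the kinase AURKA (-2.39 ± 0.09), cyclin CCNB1 (-1.66 ± 0.10) and the kinesin KIF20A (-3.12 ± 0.19). The proliferation marker MKI67 fell from 276 ± 8.41 to 42.7 ± 3.95 CPM (n = 3 and 2, log2 -2.69 ± 0.23, edgeR adjusted p = 3.98e-13). Of the DNA replication list, 1 of 14 rose, 11 fell and 2 did not pass, or 1 and 12 over the list alone (camera adjusted p = 3.63e-13). The helicase subunits MCM3 and MCM4 were at -2.11 ± 0.09 and -1.31 ± 0.06 and UHRF1 at -2.86 ± 0.15. The cytosolic heat shock list was lower (0 of 11 rose, 8 fell and 3 did not pass, or 0 and 9 over the list alone, camera adjusted p = 3.68e-05). TXNIP fell by 1.86 ± 0.14 on the log2 scale (edgeR adjusted p = 3.76e-14), while HMGCS1 (0.13 ± 0.28) and CYP1A1 (0.01 ± 0.36) did not pass. The hypoxia and glycolysis list tested higher although its median was -0.13 and its mean 0.21 (6 of 14 rose, 4 fell and 4 did not pass, or 6 and 4 over the list alone, camera adjusted p = 0.0287). The NRF2 list was higher with the preset correlation (8 of 18 rose, 2 fell and 8 did not pass, or 8 and 3 over the list alone, camera adjusted p = 0.0405, but adjusted p = 0.132 with an estimated correlation, and 0.0108 with it without the 2 libraries). The astrocyte markers were lower (1 of 7 rose, 4 fell and 2 did not pass, or 1 and 4 over the list alone, median -2.52, or -0.62 with DESeq2 factors, camera adjusted p = 0.0474, but adjusted p = 0.0558 with an estimated correlation, and 0.0886 without the 2 libraries).

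The high and low doses of Coptidis differed in the stress and cell division genes too. Between 14 and 0.56 µg/mL, 7749 genes changed (3691 higher and 4058 lower, 11678 or 5958 higher and 5720 lower without the 2 libraries). GDF15 rose by 6.97 ± 0.23, NGFR by 6.62 ± 0.26, HKDC1 by 5.29 ± 0.21 and DDIT3 by 4.67 ± 0.24. CD248 (-5.19 ± 0.40), METTL7A (-4.97 ± 0.33) and MKI67 (-2.75 ± 0.24) fell, and each of these 7 genes had an edgeR adjusted p of at most 9.48e-13. The ATF4 list rose with dose (19 of 20 rose, 1 fell and 0 did not pass, or 19 and 1 over the list alone, camera adjusted p = 2.25e-40). So did the ER chaperone list (14 of 14 rose, 0 fell and 0 did not pass, or 14 and 0 over the list alone, camera adjusted p = 3.42e-14). The mitotic list fell (0 of 15 rose, 15 fell and 0 did not pass, or 0 and 15 over the list alone, camera adjusted p = 3.42e-14). At the medium dose, DDIT3 rose by 1.67 ± 0.19 and TXNIP fell by 1.93 ± 0.14 on the log2 scale (edgeR adjusted p = 2.03e-08 and 1.85e-13). There 632 genes passed against the vehicle, 4560 without the 2 libraries and between 261 and 424 when 1 library at a time was left out.

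High-dose Bupleuri Radix raised lysosomal genes and lowered mitotic ones. KRT75 rose by 5.07 ± 0.38 (6.3 ± 0.404 against 0.187 ± 0.186 CPM, n = 3 and 3), KCP by 4.53 ± 0.29, RRAGD by 4.14 ± 0.28 and GDF15 by 4.03 ± 0.17 (73.7 ± 0.738 against 4.51 ± 0.544 CPM, n = 3 and 3). The endoplasmic reticulum calcium pump ATP2A3 (ENSG00000074370, chromosome 17, 3923870 to 3964464, minus strand) rose by 4.08 ± 0.15 (38.1 ± 1.8 against 2.27 ± 0.299 CPM, n = 3 and 3). The edgeR adjusted p of these genes was at most 1.42e-13. The homeobox gene LHX9 fell by 2.48 ± 0.21 on the log2 scale (0.669 ± 0.0854 against 3.78 ± 0.324 CPM, n = 3 and 3). KRT18, a simple-epithelium keratin (chromosome 12, 52948871 to 52952901, plus strand), fell 4.53-fold (52.9 ± 1.38 against 240.1 ± 5.4 CPM, n = 3 and 3, edgeR adjusted p = 1.2e-12). The R-spondin receptor LGR6 (-2.47 ± 0.21), the leukocyte phosphatase PTPRC (-2.15 ± 0.25), PTPRQ (-2.02 ± 0.34), CDH9 (-2.02 ± 0.34) and the cardiac actin ACTC1 (-2.28 ± 0.44) fell. SERPINB4, which can share reads with SERPINB3, was at -1.95 ± 0.30. Of the lysosome and TFEB list, 13 of 14 rose, 0 fell and 1 did not pass, or 13 and 0 over the list alone (camera adjusted p = 2.07e-25). GPNMB was at 2.05 ± 0.09, SQSTM1 at 1.95 ± 0.11 and the sialidase NEU1 at 0.95 ± 0.12. Of the MAPK and immediate-early list, 10 of 12 rose, 0 fell and 2 did not pass, or 11 and 0 over the list alone (camera adjusted p = 1.37e-17). Its phosphatases DUSP4 and DUSP6 rose by 0.85 ± 0.06 and 0.78 ± 0.08 and SPRY2 by 0.95 ± 0.08. All 15 mitotic genes fell (15 adjusted over the list alone, camera adjusted p = 3.92e-16), with KIF20A at -1.18 ± 0.15, CCNB1 at -0.67 ± 0.08 and AURKA at -0.53 ± 0.07.

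The NRF2 antioxidant list was higher after Bupleuri (8 of 18 rose, 1 fell and 9 did not pass, or 10 and 1 over the list alone, camera adjusted p = 5.11e-11). Its member HMOX1 rose by 2.21 ± 0.13 (268 ± 8.33 against 57.9 ± 1.66 CPM, n = 3 and 3, edgeR adjusted p = 6.1e-17). The ferritin light chain FTL, which can share reads with processed copies, rose by 1.96 ± 0.19 (edgeR adjusted p = 7.96e-11). Of the ATF4 list, 11 of 20 rose, 1 fell and 8 did not pass, or 11 and 1 over the list alone (camera adjusted p = 4.27e-11), with STC2 at 0.80 ± 0.07 and SESN2 at 0.90 ± 0.10. DDIT3 (1.11 ± 0.17), CDKN1A (0.91 ± 0.11) and IL6 (0.88 ± 0.15) rose and TXNIP (-0.81 ± 0.11) and MKI67 (-0.78 ± 0.18) fell, with edgeR adjusted p of at most 0.00159. The NF-kB list was higher (7 of 13 rose, 1 fell and 5 did not pass, or 7 and 1 over the list alone, camera adjusted p = 6.23e-06). So was the p53 list (4 of 16 rose, 0 fell and 12 did not pass, or 4 and 0 over the list alone, camera adjusted p = 0.00146). DNA replication genes were lower (0 of 14 rose, 8 fell and 6 did not pass, or 0 and 8 over the list alone, camera adjusted p = 3.77e-07). Extracellular matrix and TGF-beta genes were lower as well (0 of 14 rose, 6 fell and 8 did not pass, or 1 and 9 over the list alone, camera adjusted p = 3.75e-08). The LXR cholesterol efflux list moved the same way (0 of 5 rose, 3 fell and 2 did not pass, or 1 and 4 over the list alone, camera adjusted p = 0.000112). The epithelial marker list was lower too (1 of 4 rose, 2 fell and 1 did not pass, or 1 and 2 over the list alone, camera adjusted p = 0.0032, but adjusted p = 0.0588 with an estimated correlation, and 5e-06 with it without the 2 libraries). The hypoxia and glycolysis list tested higher with a median of -0.02 and a mean of 0.21 (5 of 14 rose, 3 fell and 6 did not pass, or 5 and 6 over the list alone, camera adjusted p = 0.0412, but adjusted p = 0.0573 without the 2 libraries). In all 2477 genes passed, with 1481 higher and 996 lower, and 6987 passed without the 2 libraries.

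Between the high and low doses of Bupleuri, 2361 genes changed (1259 higher and 1102 lower, 6936 or 3759 higher and 3177 lower without the 2 libraries). GDF15 (3.96 ± 0.16), ATP2A3 (3.75 ± 0.14), KRT75 (4.17 ± 0.32), KCP (3.85 ± 0.26) and HMOX1 (2.16 ± 0.13) rose with dose. LGR6 (-2.73 ± 0.20), LHX9 (-2.33 ± 0.20), CDH9 (-2.52 ± 0.31) and TXNIP (-1.14 ± 0.11) fell, and all 9 genes had an edgeR adjusted p of at most 6.17e-08. The lysosome list rose with dose (12 of 14 rose, 0 fell and 2 did not pass, or 13 and 0 over the list alone, camera adjusted p = 5.14e-24). The mitotic list fell with it (0 of 15 rose, 14 fell and 1 did not pass, or 0 and 14 over the list alone, camera adjusted p = 4.61e-12).

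High-dose Zizyphi Fructus, the sugar-rich jujube fruit, raised TXNIP, whose product restrains glucose uptake (ENSG00000265972, chromosome 1, 145992435 to 145996600, minus strand), 24.9-fold (log2 4.64 ± 0.12, 214 ± 4.53 against 8.6 ± 0.615 CPM, n = 2 and 3, edgeR adjusted p = 2.72e-29). Its arrestin relative ARRDC4 rose by 2.07 ± 0.20 (25 ± 0.502 against 5.93 ± 0.567 CPM, n = 2 and 3, edgeR adjusted p = 3.15e-09). The list of glucose-responsive MondoA targets, of 3 genes, had 2 that rose, 0 that fell and 1 that did not pass (2 and 0 adjusted over the list alone, camera adjusted p = 1.86e-108). The transcription factor EGR1 rose by 1.38 ± 0.18 and LINC00663 by 1.43 ± 0.24 (edgeR adjusted p = 6.28e-06 and 0.000379). Much of the EGR1 value was present at low doses, where EGR1 lay 0.83 to 1.21 above the vehicle in all 7 extracts without the 2 libraries. The cytokine TNFSF15 fell by 1.29 ± 0.18 on the log2 scale (4.71 ± 0.0656 against 11.5 ± 0.615 CPM, n = 2 and 3, edgeR adjusted p = 3.21e-05). The metallothionein MT1E, whose reads can be shared with other metallothioneins, was at -1.46 ± 0.26. Its list was lower (0 of 6 rose, 1 fell and 5 did not pass, or 0 and 4 over the list alone, camera adjusted p = 9.81e-05). The ER chaperone list was lower (0 of 14 rose, 2 fell and 12 did not pass, or 0 and 2 over the list alone, camera adjusted p = 2.48e-05). HSPA5 was at -0.48 ± 0.09 (2663 ± 28.8 against 3709 ± 34.9 CPM, n = 2 and 3), and its edgeR adjusted p of 0.00141 became 0.0582 without replicate 3. The MAPK list was higher (3 of 12 rose, 1 fell and 8 did not pass, or 3 and 1 over the list alone, camera adjusted p = 0.000453, but adjusted p = 0.0813 with an estimated correlation without the 2 libraries), with DUSP6 at 0.65 ± 0.08. The cholesterol list was lower (0 of 24 rose, 2 fell and 22 did not pass, or 0 and 2 over the list alone, camera adjusted p = 0.0118). HMOX1 (-0.29 ± 0.14), DDIT3 (-0.27 ± 0.19), CYP1A1 (0.30 ± 0.34) and MKI67 (0.37 ± 0.20) did not pass.

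The TXNIP response to Zizyphi followed dose. TXNIP was at 0.72 ± 0.12 against the vehicle at the medium dose (edgeR adjusted p = 0.00199, or 0.0878 without medium-dose replicate 3), and the high dose lay above the low by 4.38 ± 0.13 (edgeR adjusted p = 5.79e-26). ARRDC4 rose by 2.07 ± 0.22 and TNFSF15 fell by 1.31 ± 0.19 between those doses (edgeR adjusted p = 8.16e-08 and 0.000187). Between the high and low doses 27 genes passed, 1287 without the 2 libraries and between 3 and 8 when 1 library at a time was left out. Against the vehicle, the high dose gave 277 genes (159 higher and 118 lower), 3785 (1658 higher and 2127 lower) without the 2 libraries and between 52 and 154 with 1 library left out.

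High-dose Citri Unshius Pericarpium, the peel of the satsuma mandarin, also raised TXNIP, by 3.93 ± 0.11 (131 ± 9.78 against 8.6 ± 0.615 CPM, n = 3 and 3, edgeR adjusted p = 1.5e-27). ARRDC4 rose by 1.55 ± 0.18 (edgeR adjusted p = 2.38e-07). PDK4, a kinase that inhibits pyruvate dehydrogenase, rose by 1.71 ± 0.33 (4.35 ± 0.286 against 1.31 ± 0.234 CPM, n = 3 and 3) and ACTC1 by 1.78 ± 0.30. IL6 rose by 1.28 ± 0.15 (9.65 ± 1.01 against 3.95 ± 0.659 CPM, n = 3 and 3), and these 3 genes had an edgeR adjusted p of at most 0.000683. LGR6 fell by 1.74 ± 0.19 on the log2 scale (1.95 ± 0.412 against 6.61 ± 1.06 CPM, n = 3 and 3, chromosome 1, 202193901 to 202319781, plus strand). PTPRB (-1.36 ± 0.20), TNFSF15 (-1.24 ± 0.16), PADI2 (-1.12 ± 0.12), VSNL1 (-1.14 ± 0.23), FAM13B (-1.29 ± 0.29) and the hair keratin-associated KRTAP1-5 (-1.61 ± 0.27) also fell, all with an edgeR adjusted p of at most 0.00392. The near-identical serpins SERPINB3 (1.68 ± 0.20) and SERPINB4 (1.76 ± 0.22) rose, as values that may share reads. The MondoA target list had 2 of 3 genes higher, 0 lower and 1 that did not pass (2 and 0 adjusted over the list alone, camera adjusted p = 2.46e-57). Of the MAPK list, 5 of 12 rose, 0 fell and 7 did not pass, or 6 and 0 over the list alone (camera adjusted p = 1.85e-05). EGR1 was at 1.14 ± 0.17, FOS at 1.09 ± 0.19 and DUSP6 at 0.60 ± 0.08, but EGR1 and FOS were already 0.83 to 1.21 and 0.66 to 1.18 higher at the low doses of all extracts. The NF-kB list was higher (6 of 13 rose, 1 fell and 6 did not pass, or 7 and 1 over the list alone, camera adjusted p = 0.000169, but adjusted p = 0.089 with an estimated correlation without the 2 libraries). Cholesterol synthesis and uptake genes were lower as a list (1 of 24 rose, 4 fell and 19 did not pass, or 2 and 7 over the list alone, camera adjusted p = 7.79e-05), with INSIG1 at -0.58 ± 0.08. HMOX1 (0.04 ± 0.12) and DDIT3 (0.19 ± 0.17) did not pass.

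With dose, TXNIP rose by 3.69 ± 0.11 between 20 and 500 µg/mL of Citri (edgeR adjusted p = 6.87e-27), ARRDC4 by 1.57 ± 0.18, SERPINB3 by 1.43 ± 0.19 and IL6 by 0.82 ± 0.14. LGR6 (-1.80 ± 0.19), PADI2 (-1.15 ± 0.12) and IRAG1 (-1.17 ± 0.18) fell, and the edgeR adjusted p of these genes was at most 0.000887. At 100 µg/mL TXNIP was 0.59 ± 0.11 above the vehicle (edgeR adjusted p = 0.00252). The extracellular matrix list was lower with dose (0 of 14 rose, 1 fell and 13 did not pass, or 0 and 1 over the list alone, camera adjusted p = 2.25e-05). The NF-kB list rose with dose (2 of 13 rose, 0 fell and 11 did not pass, or 7 and 0 over the list alone, camera adjusted p = 3.22e-08). Between the doses 188 genes passed (2408 without the 2 libraries), and between 52 and 106 when 1 library at a time was left out. Against the vehicle the high dose gave 814 genes (514 higher and 300 lower, 5526 or 2531 higher and 2995 lower without the 2 libraries), and between 400 and 558 with 1 library left out.

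High-dose Cimicifugae Rhizoma raised genes of the NRF2 and aryl hydrocarbon receptor (AhR) responses. HMOX1 (ENSG00000100292, chromosome 22, 35380361 to 35394214, plus strand) rose 8.35-fold (log2 3.06 ± 0.13, 483 ± 18.4 against 57.9 ± 1.66 CPM, n = 3 and 3, edgeR adjusted p = 1.73e-20). The quinone reductase NQO1 rose by 0.87 ± 0.13 and FTL by 1.18 ± 0.18. Of the NRF2 list, 9 of 18 rose, 0 fell and 9 did not pass, or 12 and 0 over the list alone (camera adjusted p = 1.5e-20). Of the AhR list, 5 of 6 rose, 0 fell and 1 did not pass, or 6 and 0 over the list alone (camera adjusted p = 7.8e-14). Its aldehyde dehydrogenase ALDH3A1 rose by 2.50 ± 0.32 (2.61 ± 0.578 against 0.454 ± 0.147 CPM, n = 3 and 3). The xenobiotic oxygenase CYP1A1 (chromosome 15, 74719542 to 74725610, minus strand) rose by 1.69 ± 0.28 (2.9 ± 0.734 against 0.905 ± 0.404 CPM, n = 3 and 3). CYP1B1 went from 162 ± 1.05 to 326 ± 11.3 CPM (n = 3 and 3). TXNIP rose by 1.89 ± 0.11 (31.9 ± 1.8 against 8.6 ± 0.615 CPM, n = 3 and 3, edgeR adjusted p = 8.96e-17). The sterol reductase TM7SF2 rose by 1.56 ± 0.28, PDK4 by 1.48 ± 0.33, the channel PANX2 by 1.44 ± 0.28, GALNT15 by 1.39 ± 0.24, the lncRNA LUCAT1 by 1.36 ± 0.17 and CDKN1A by 0.83 ± 0.11 (edgeR adjusted p of at most 0.00316). The oxytocin receptor OXTR fell by 1.49 ± 0.11 on the log2 scale (7.48 ± 0.869 against 21 ± 2.02 CPM, n = 3 and 3, chromosome 3, 8750408 to 8769628, minus strand). KRT18 (-1.18 ± 0.17), PTPRB (-1.30 ± 0.20), ANXA3 (-1.24 ± 0.15), LGR6 (-1.23 ± 0.19), TRPC4 (-1.20 ± 0.16) and the antisense gene ZFHX4-AS1 (-1.29 ± 0.24) fell too, all with edgeR adjusted p of at most 0.000294. The ATF4 list was higher (7 of 20 rose, 0 fell and 13 did not pass, or 12 and 0 over the list alone, camera adjusted p = 2.14e-06). DDIT4 was at 0.63 ± 0.10 and CEBPB at 0.89 ± 0.20, but DDIT3 did not pass (0.30 ± 0.17). The extracellular matrix list was lower (0 of 14 rose, 3 fell and 11 did not pass, or 0 and 4 over the list alone, camera adjusted p = 1.38e-05, but adjusted p = 0.0521 with an estimated correlation, and 0.00213 with it without the 2 libraries). ACTA2 was at -0.86 ± 0.12 and CCN2 at -0.76 ± 0.10.

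HMOX1 and TXNIP passed at every dose of Cimicifugae. HMOX1 was 1.16 ± 0.12, 2.21 ± 0.13 and 3.06 ± 0.13 above the vehicle at 20, 100 and 500 µg/mL, and TXNIP 0.76 ± 0.11, 1.15 ± 0.10 and 1.89 ± 0.11 (largest edgeR adjusted p = 4.16e-05). Between the high and low doses HMOX1 (1.90 ± 0.13), CYP1A1 (1.55 ± 0.27), the lipase inhibitor ANGPTL4 (1.54 ± 0.17), TXNIP (1.13 ± 0.10) and SCIRT (1.20 ± 0.23) rose. LGR6 (-1.57 ± 0.18) and the neurofilament NEFL (-0.98 ± 0.14) fell, and the edgeR adjusted p of all 7 was at most 0.00254. Of the NRF2 list, 3 of 18 rose, 0 fell and 15 did not pass, or 11 and 0 over the list alone (camera adjusted p = 9.14e-29). Of the AhR list, 4 of 6 rose, 0 fell and 2 did not pass, or 6 and 0 over the list alone (camera adjusted p = 4.22e-22). Between these doses 109 genes passed, 1843 without the 2 libraries and between 52 and 62 when 1 library at a time was left out. Against the vehicle the counts were 1245 at the high dose (840 higher and 405 lower), 6317 (2865 higher and 3452 lower) without the 2 libraries and between 683 and 848 with 1 library left out. At the medium dose 704 genes passed, and between 315 and 539 with 1 library left out.

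Citri and Cimicifugae were deposited under one set number and shared doses, so their high doses were compared directly at 500 µg/mL. TXNIP was 4.11-fold higher in Citri (log2 2.04 ± 0.10, 131 ± 9.78 against 31.9 ± 1.8 CPM, n = 3 and 3, edgeR adjusted p = 6.43e-19). HMOX1 was 8.15-fold lower (-3.03 ± 0.13, 59.3 ± 2.74 against 483 ± 18.4 CPM, n = 3 and 3, edgeR adjusted p = 2.3e-20). ARRDC4 (1.21 ± 0.18), the matricellular gene CCN1 (0.80 ± 0.09) and DIRAS3 (0.75 ± 0.08) were higher in Citri, and THBD, the thrombomodulin gene (-1.09 ± 0.12), and the VIP receptor VIPR1 (-1.08 ± 0.16) lower, with edgeR adjusted p of at most 8.17e-05. CYP1A1 was at -1.20 ± 0.26 (edgeR adjusted p = 0.0166), ANKRD1 at 0.74 ± 0.16 (0.0127) and KRTAP1-5 at -1.15 ± 0.28 (0.0495). Leaving out replicate 3 of high-dose Citri ended those 3 calls, at edgeR adjusted p = 0.18, 0.105 and 0.46, as did leaving out replicate 2 of Citri or replicate 1 or 3 of Cimicifugae. In all 59 genes differed (17 higher and 42 lower), 1193 (654 higher and 539 lower) without the 2 libraries and between 25 and 36 when 1 of their own libraries was left out.

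High-dose Aconiti Lateralis Radix Preparata, the processed lateral root of aconite, raised HMOX1 10.7-fold (log2 3.42 ± 0.13, 619 ± 218 against 57.9 ± 1.66 CPM, n = 3 and 3, edgeR adjusted p = 5.08e-22) and immediate-early genes. FOS (chromosome 14, 75278774 to 75282230, plus strand) rose by 2.22 ± 0.19 (7.71 ± 2.29 against 1.63 ± 0.222 CPM, n = 3 and 3; log2 0.66 to 1.18 at the low doses of all 7 extracts without the 2 libraries), FOSB by 2.18 ± 0.23 and NR4A1 by 1.60 ± 0.16. RASD1 (1.99 ± 0.28), CYP2S1 (1.76 ± 0.13), IL1B (1.67 ± 0.13), ANGPTL4 (1.61 ± 0.18) and IL6 (1.47 ± 0.15) rose too, and the edgeR adjusted p of these 8 genes was at most 2.98e-06. Without replicate 1 of this group and the divergent Yijung-tang library these 9 values were, in the order named, 3.08, 1.98, 1.96, 1.28, 1.64, 1.53, 1.52, 1.24 and 1.43. The diacylglycerol kinase DGKB fell by 1.81 ± 0.19 (2.76 ± 1.49 against 10.5 ± 0.0876 CPM, n = 3 and 3, chromosome 7, 14145049 to 14974777, minus strand). The neurexin NRXN3 (-1.66 ± 0.20), the channel TRPC4 (-1.50 ± 0.17), ADGRL3 (-1.37 ± 0.21), RIMS1 (-1.31 ± 0.20), DNM3 (-1.27 ± 0.17) and the sterol synthase HMGCS1 (-1.18 ± 0.26) fell, with edgeR adjusted p of at most 0.000996. In the order named, these 7 values became -1.54, -1.59, -1.38, -1.20, -1.22, -1.19 and -0.73 without the same 2 libraries. CYP1A1 rose 2.47-fold (2.32 ± 0.7 against 0.905 ± 0.404 CPM, n = 3 and 3, edgeR adjusted p = 0.0012; log2 1.08 without the same libraries).

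Of the MAPK and immediate-early list, 11 of 12 rose, 0 fell and 1 did not pass, or 11 and 0 over the list alone (camera adjusted p = 4.41e-17). The NRF2 list was higher (10 of 18 rose, 1 fell and 7 did not pass, or 12 and 1 over the list alone, camera adjusted p = 3.3e-08), with FTH1 at 1.24 ± 0.17 (1.10 without the 2 libraries). The NF-kB list was higher (9 of 13 rose, 0 fell and 4 did not pass, or 10 and 1 over the list alone, camera adjusted p = 3.3e-08), with LIF at 0.94 ± 0.14 (then 0.61). The ATF4 list followed (14 of 20 rose, 2 fell and 4 did not pass, or 15 and 2 over the list alone, camera adjusted p = 2.04e-07), with SESN2 at 0.71 ± 0.10 (then 0.45) and GDF15 at 1.52 ± 0.17 (then 1.26). AhR targets were higher as well (4 of 6 rose, 0 fell and 2 did not pass, or 4 and 0 over the list alone, camera adjusted p = 0.0132). Of the glucocorticoid list, 5 of 6 rose, 1 fell and 0 did not pass, or 5 and 1 over the list alone (camera adjusted p = 0.000755). Of the cholesterol list, 3 of 24 rose, 9 fell and 12 did not pass, or 3 and 9 over the list alone (camera adjusted p = 0.0447). Without the 2 libraries the genes that rose and fell were, in the order of these lists, 11 and 0, 15 and 1, 12 and 0, 17 and 0, 6 and 0, 4 and 1 and 2 and 13, and the ATF4 median went from 0.52 to 0.33. High-dose Aconiti had 5362 genes past the test (3159 higher and 2203 lower), 4858 (2229 higher and 2629 lower) without the 2 libraries and between 1885 (without high-dose replicate 1) and 8550 (without high-dose replicate 3) when 1 library at a time was left out. A fit of only the 6 libraries compared called 0 genes (edgeR, 1402 with an unadjusted p under 0.05), and DESeq2 with all libraries called 6029. The number therefore depended on replicate 1 and on which other libraries entered the fit.

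Between 500 and 20 µg/mL of Aconiti, HMOX1 (2.56 ± 0.13), ANGPTL4 (1.99 ± 0.18), FOSB (1.88 ± 0.22), RASD1 (1.60 ± 0.26) and IL6 (1.15 ± 0.15) rose. NRXN3 (-1.57 ± 0.20), DGKB (-1.43 ± 0.19) and PAPLN (-1.32 ± 0.24) fell, all 8 with edgeR adjusted p of at most 0.000479. In that order they were 2.23, 1.64, 1.66, 1.26, 1.13, -1.48, -1.17 and -1.43 without the 2 libraries. HMOX1 also passed at the medium dose (2.18 ± 0.13, edgeR adjusted p = 1.03e-15) and at the low dose (0.86 ± 0.12, 0.000172). The MAPK list rose with dose (10 of 12 rose, 0 fell and 2 did not pass, or 10 and 0 over the list alone, camera adjusted p = 2.21e-18). So did the NF-kB list (8 of 13 rose, 0 fell and 5 did not pass, or 11 and 0 over the list alone, camera adjusted p = 6.29e-16). Between the high and low doses 1566 genes passed, 1674 without the 2 libraries and between 547 (without high-dose replicate 1) and 6298 (without high-dose replicate 3) when 1 library at a time was left out. With only the 6 libraries compared it was 0 (edgeR, 493 with an unadjusted p under 0.05), and with DESeq2 2271.

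The formula Yijung-tang raised ATF4 and NRF2 target genes at its high dose. GDF15 rose 5.36-fold (log2 2.42 ± 0.17, 24.2 ± 1.9 against 4.51 ± 0.544 CPM, n = 2 and 3). CHAC1, which degrades glutathione (chromosome 15, 40952962 to 40956519, plus strand), rose by 1.84 ± 0.17 (12.6 ± 0.0546 against 3.53 ± 0.758 CPM, n = 2 and 3). TRIB3 rose by 1.32 ± 0.14 and the NKG2D ligand ULBP1 by 2.07 ± 0.33, and the 4 genes had an edgeR adjusted p of at most 7.29e-05. Of the ATF4 list, 14 of 20 rose, 0 fell and 6 did not pass, or 17 and 0 over the list alone (camera adjusted p = 5.48e-42). HMOX1 rose by 1.73 ± 0.14 (192 ± 3.8 against 57.9 ± 1.66 CPM, n = 2 and 3, edgeR adjusted p = 1e-11), and SQSTM1 by 1.12 ± 0.12. KCP (2.24 ± 0.34) and ATP2A3 (1.82 ± 0.16) rose. FTL (1.70 ± 0.20) and its processed copy FTLP3 (1.85 ± 0.36), which can share reads, rose as well. Of the NRF2 list, 11 of 18 rose, 0 fell and 7 did not pass, or 13 and 0 over the list alone (camera adjusted p = 6.61e-29). The chemokine CCL2 fell by 1.32 ± 0.14 (9.06 ± 0.386 against 22.6 ± 2.27 CPM, n = 2 and 3). OXTR (-1.22 ± 0.12), SLC27A2 (-1.21 ± 0.20), KRT18 (-1.18 ± 0.20), NRXN3 (-1.18 ± 0.21), RIMS1 (-1.16 ± 0.22) and TXNIP (-0.75 ± 0.13) fell, with edgeR adjusted p of at most 0.000591. Of the ER chaperone list, 5 of 14 rose, 0 fell and 9 did not pass, or 7 and 0 over the list alone (camera adjusted p = 1.21e-06). HSPA5 was at 0.52 ± 0.09, calreticulin CALR at 0.67 ± 0.13 and HERPUD1 at 0.51 ± 0.08.

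The mitotic list was lower after high-dose Yijung-tang (0 of 15 rose, 3 fell and 12 did not pass, or 0 and 8 over the list alone, camera adjusted p = 1.54e-10). So was the DNA replication list (0 of 14 rose, 1 fell and 13 did not pass, or 0 and 5 over the list alone, camera adjusted p = 0.00142). The extracellular matrix list was lower too (0 of 14 rose, 5 fell and 9 did not pass, or 0 and 6 over the list alone, camera adjusted p = 1.48e-07), with CCN2 at -0.68 ± 0.12. The lysosome list was higher (4 of 14 rose, 0 fell and 10 did not pass, or 7 and 0 over the list alone, camera adjusted p = 2.27e-06). DDIT3 rose by 0.88 ± 0.19, with an edgeR adjusted p of 0.00243 that became 0.056 without replicate 2. In all 770 genes passed (528 higher and 242 lower), 5421 (2499 higher and 2922 lower) without the 2 libraries and between 234 and 500 when 1 library at a time was left out. Between the high and low doses GDF15 (1.91 ± 0.19), KCP (2.00 ± 0.38) and NMRAL2P (1.92 ± 0.24) rose (edgeR adjusted p of at most 0.000275), and they did so without the 2 libraries (2.49, 1.93 and 1.83). PRAL (-4.55 ± 1.14) and MVP-DT (-2.56 ± 0.42) were among the largest falls with dose, and stood at -1.14 and -0.30 without the 2 libraries (edgeR adjusted p = 0.707 and 0.63). Low-dose replicate 1 set the 4354 genes between doses and 5756 at the low dose, which became 1191 and 499 without the 2 libraries. Both were 0 with only the groups compared (edgeR, 125 and 787 with an unadjusted p under 0.05), and 4658 and 5980 with DESeq2. Leaving out single libraries gave between 185 (without low-dose replicate 1) and 10555 (without low-dose replicate 2) between doses. At the low dose they gave between 4 (without low-dose replicate 1) and 11114 (without low-dose replicate 2).

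Banhasasim-tang, whose recipe includes Coptidis Rhizoma, had 1 library per dose, so its genes are described without a test. In the high-dose library GDF15 stood at 267 CPM (95% Poisson interval, for counting error only, 261 to 273) against 4.38 ± 0.53, n = 1 and 3, a log2 difference of 5.91, followed by 3.10 and 0.52 at the medium and low doses. DDIT3 stood at 322 CPM (Poisson interval 315 to 328) against 24.5 ± 0.589, n = 1 and 3 (log2 3.71, 1.59 and 0.21 from high to low dose). HKDC1 (4.34), NGFR (4.04), TRIB3 (3.98), ADM2 (3.89), ATF3 (3.78), HMOX1 (2.57) and IL6 (2.54) were higher than in the vehicle, as was the mitochondrial ribosomal RNA MT-RNR1 (4.64). TCAF2 (-3.02), NDST3 (-2.75), the integrin ITGB8 (-2.63), VAV3 (-2.59), DIO2 (-2.51), PTPRC (-2.18), SYT12 (-2.17), LGR6 (-2.11), MKI67 (-1.64) and TXNIP (-0.83) were lower. Of 11067 genes with a mean of at least 5 CPM, 240 were at least 2-fold higher and 251 lower. The median log2 difference was 1.88 for the ATF4 list, 1.02 for the ER chaperone list, 0.90 for the NRF2 list, 0.69 for the MAPK list and 0.67 for the NF-kB list, in which 5 of 10 genes lay above and 3 below every vehicle library. It was -0.80 for the mitotic list, -0.69 for the DNA replication list and -0.72 for the astrocyte markers. As a description of this library and no test of the formula, those lists lay at percentile 99.98 or above and at percentile 0.21 or below among 10000 random lists matched for expression.

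The genes fixed in advance passed in different extracts, with differences tested only between Citri and Cimicifugae. After high-dose Aconiti TXNIP lay 0.38 ± 0.11 above the vehicle but only 0.12 ± 0.10 above the low dose (edgeR adjusted p = 0.00829 and 0.448). CDKN1A passed in all extracts but Zizyphi (0.25 ± 0.13), with 0.91 ± 0.12 in Aconiti and 0.66 ± 0.13 in Yijung-tang (edgeR adjusted p = 4.48e-07 and 0.000745). IL6 passed in Cimicifugae (0.80 ± 0.16, edgeR adjusted p = 0.00056) but not in Zizyphi (0.38 ± 0.17) or Yijung-tang (0.51 ± 0.17). At low doses mean CDKN1A was 21.5 to 29.45 CPM (vehicle 20.8) and IL6 4.48 to 5.47 (3.95). CYP1A1 passed only in Cimicifugae and Aconiti (0.48 ± 0.30 in Citri) and MKI67 only in Coptidis and Bupleuri (-0.43 ± 0.20 in Yijung-tang). HMGCS1 passed only in Aconiti (-0.66 ± 0.25 in Citri, -0.63 ± 0.26 in Cimicifugae), but its size there rests on the divergent library. Without the 2 libraries it passed in all 7 extracts, higher in Coptidis (0.13) and lower in the others (-0.73 in Aconiti to -0.32 in Yijung-tang), but it was also lower at all low doses (-0.48 in Bupleuri to -0.33 in Coptidis). CDKN1A (0.25), MKI67 (0.36) and HMOX1 (-0.30) then passed in Zizyphi and MKI67 (-0.44) and IL6 (0.50) in Yijung-tang (largest edgeR adjusted p = 0.0193).

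**Figure D1:**
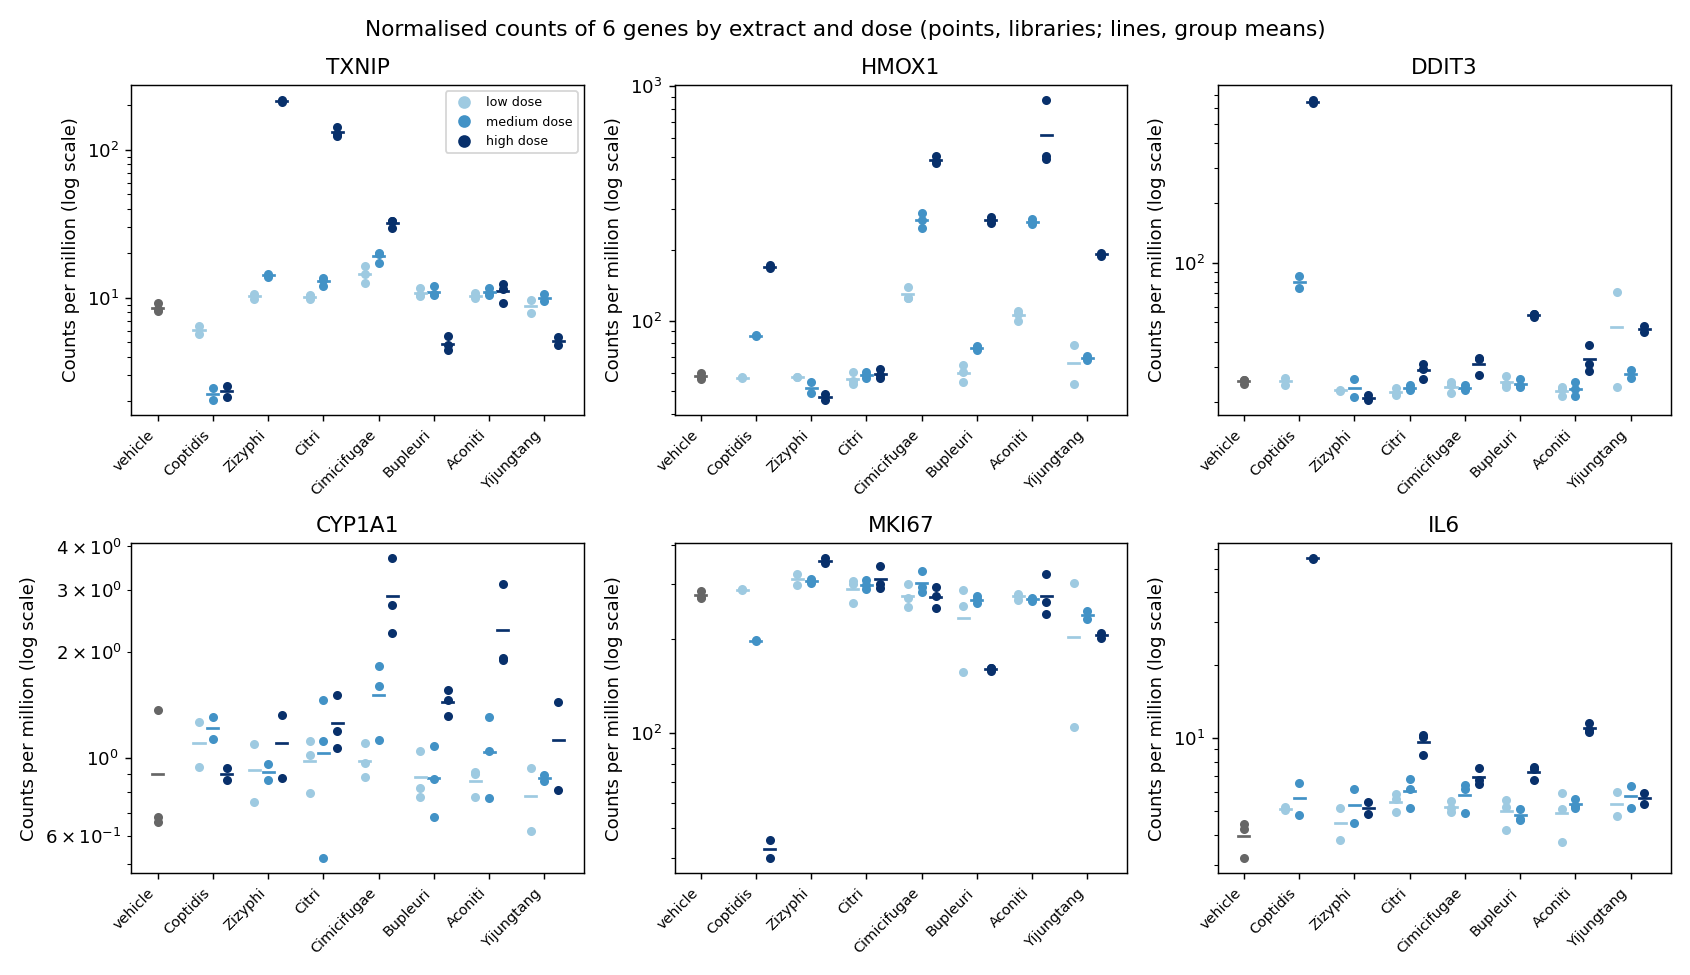
CPM of TXNIP, HMOX1, DDIT3, CYP1A1, MKI67 and IL6 in each library by extract and dose, on log axes. Mean TXNIP was 214 CPM at high-dose Zizyphi (vehicle 8.6) and mean HMOX1 619 at high-dose Aconiti (57.9).

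Several lists moved alike in a number of extracts. Besides Zizyphi, Citri and Aconiti, cholesterol genes were lower in Cimicifugae (2 of 24 rose, 3 fell and 19 did not pass, or 2 and 8 over the list alone, camera adjusted p = 0.00377). They were lower in Bupleuri as well (1 of 24 rose, 7 fell and 16 did not pass, or 1 and 8 over the list alone, camera adjusted p = 0.0478, but adjusted p = 0.0669 with an estimated correlation without the 2 libraries). Part of this was present at low doses, where the list had medians of -0.092 to -0.047 without the 2 libraries. The glucocorticoid list was higher in Citri (1 of 6 rose, 0 fell and 5 did not pass, or 4 and 0 over the list alone, camera adjusted p = 4.65e-05). It was higher in Cimicifugae too (4 of 6 rose, 0 fell and 2 did not pass, or 4 and 0 over the list alone, camera adjusted p = 0.0012). In Cimicifugae the hypoxia and glycolysis list was higher (3 of 14 rose, 0 fell and 11 did not pass, or 3 and 1 over the list alone, camera adjusted p = 0.00101). The MAPK list was higher there (5 of 12 rose, 1 fell and 6 did not pass, or 7 and 1 over the list alone, camera adjusted p = 2.24e-05, but adjusted p = 0.0561 with an estimated correlation without the 2 libraries). The MondoA list rose there with TXNIP as its only called gene (1 of 3 rose, 0 fell and 2 did not pass, or 1 and 1 over the list alone, camera adjusted p = 6.06e-07). The mitochondrially encoded respiratory chain list was higher with the preset correlation in 5 extracts at the high dose, with medians from 0.38 in Zizyphi to 0.50 in Yijung-tang. It was not particular to that dose, since the low doses had medians of 0.21 to 0.56 without the 2 libraries. None of those 5 calls held with an estimated correlation, the lowest being Yijung-tang (camera adjusted p = 3.68e-05, but adjusted p = 0.197 with an estimated correlation). The fatty acid synthesis list was lower in Citri (camera adjusted p = 0.0188, but adjusted p = 0.201 with an estimated correlation, and 0.015 with it without the 2 libraries) and Bupleuri (camera adjusted p = 0.00477, but adjusted p = 0.151 with an estimated correlation, and 0.0029 with it without the 2 libraries). It fell with dose in Citri (0 of 10 rose, 2 fell and 8 did not pass, or 0 and 2 over the list alone, camera adjusted p = 0.00014). The interferon-stimulated list was called in none of the high-dose comparisons (in Bupleuri camera adjusted p = 0.202).

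Markers of cell types were read in the same way. Astrocyte markers were lower in Zizyphi (0 of 7 rose, 1 fell and 6 did not pass, or 0 and 1 over the list alone, median -0.23, camera adjusted p = 0.00443). In Citri they were lower too (0 of 7 rose, 1 fell and 6 did not pass, or 0 and 2 over the list alone, camera adjusted p = 0.00315). The same held for Cimicifugae (0 of 7 rose, 2 fell and 5 did not pass, or 0 and 2 over the list alone, camera adjusted p = 0.00377) and for Yijung-tang (0 of 7 rose, 0 fell and 7 did not pass, or 0 and 1 over the list alone, camera adjusted p = 0.034, but adjusted p = 0.0675 with an estimated correlation without the 2 libraries). Epithelial markers fell with dose in Bupleuri (0 of 4 rose, 2 fell and 2 did not pass, or 1 and 2 over the list alone, camera adjusted p = 0.0012). Microglia and leukocyte markers, PTPRC among them, were lower with dose in Bupleuri (1 of 4 rose, 2 fell and 1 did not pass, or 1 and 3 over the list alone, camera adjusted p = 0.0499, but adjusted p = 0.0662 with an estimated correlation, and 0.0715 without the 2 libraries). Endothelial markers passed in no comparison of a high dose (lowest camera adjusted p = 0.173). Of the oligodendrocyte markers only 2 of 6 genes had enough counts, so that list was not tested.

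**Figure D2:**
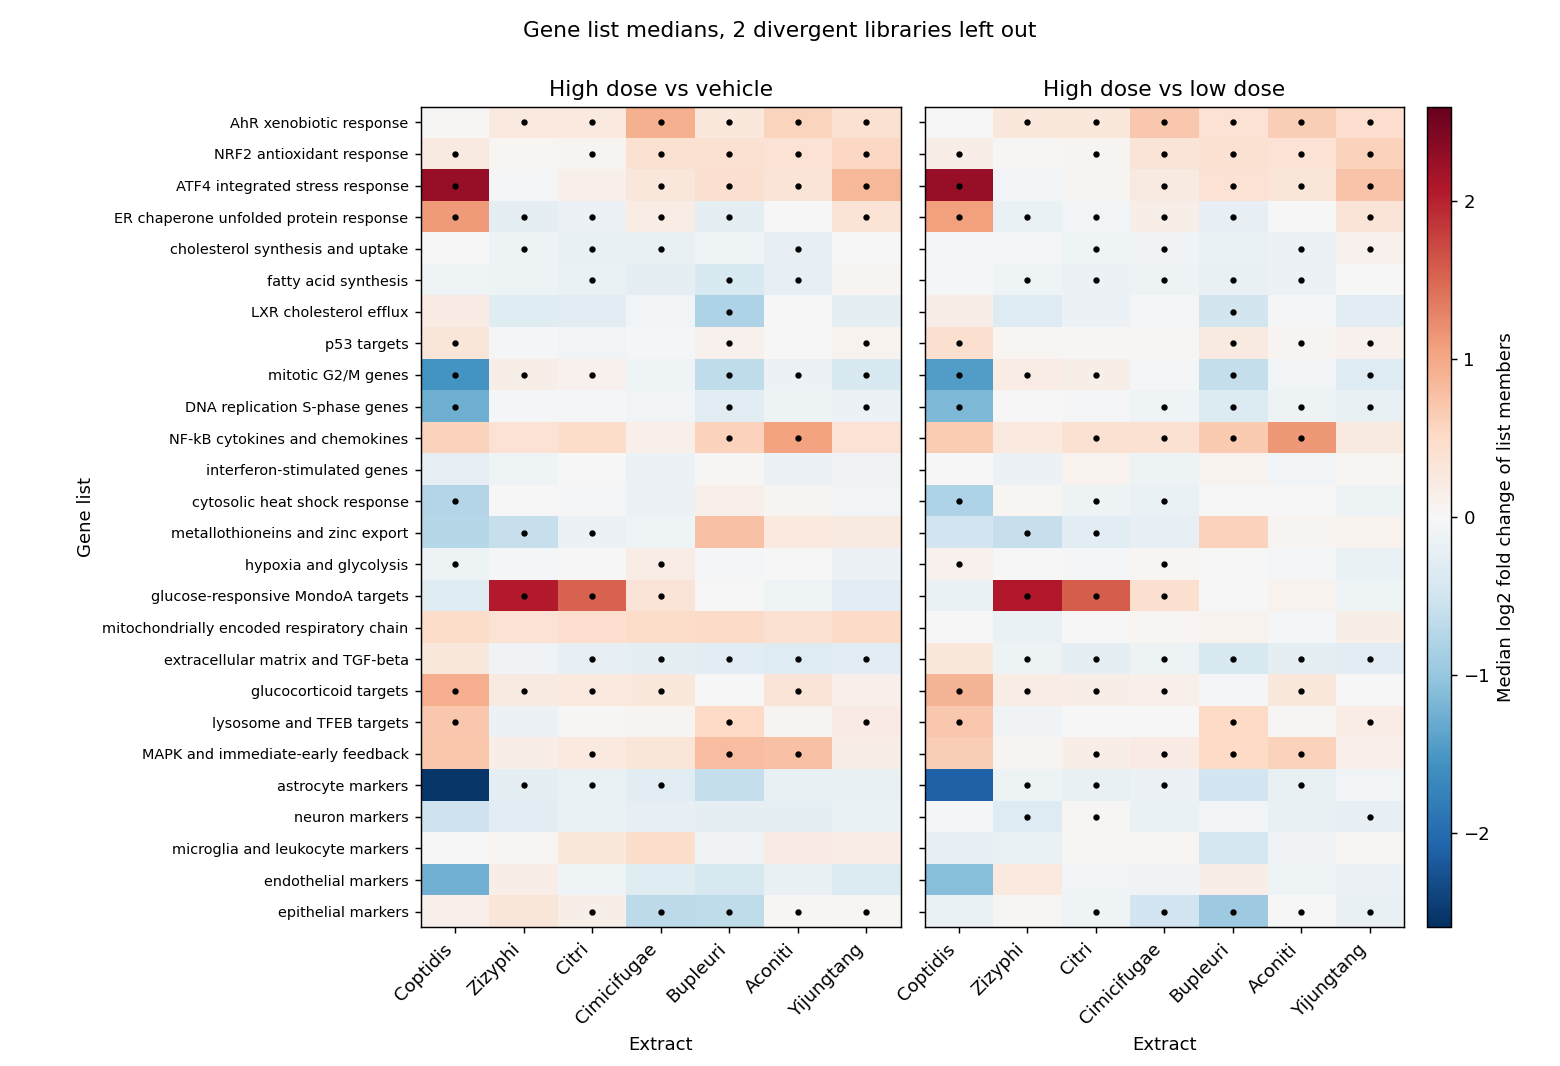
Median log2 fold change of each gene list in the high-dose comparisons, without the 2 divergent libraries, with dots where the camera adjusted p is under 0.05 with an estimated correlation. With all libraries the ATF4 list has a median of 2.26 in Coptidis and 0.86 in Yijung-tang, and the MondoA list 2.07 in Zizyphi and 1.55 in Citri.

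Of the 21 pairs of extracts, Coptidis and Bupleuri had the highest Pearson correlation of high-to-low log2 fold changes over all genes, 0.32 (Spearman 0.337). They shared 729 higher (260.5 for independent lists) and 752 lower genes (250.7), with 233 called in opposite directions. GDF15, KRT75 and HMOX1 were among those higher in both. Each extract had its own libraries, so no library entered both sides. The lowest Pearson correlation of a pair was -0.03 and the median 0.07 (0.15 over genes with a mean of at least 10 CPM). Over those genes Zizyphi and Citri, which both raised TXNIP and ARRDC4, were highest (0.69), then Citri and Cimicifugae (0.58). Against the common vehicle the median was 0.53, where simulated data without extract effects gave 0.46 through shared controls. A difference of correlations does not measure a shared effect, and part may come from shared controls or the low-dose offset against the vehicle. For Coptidis and Bupleuri the covariance against the vehicle was 0.328, 0.248 above the simulated value. Separate vehicle libraries for each extract of a pair were not compared, since 1 would have had a single library.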

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

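The test of the difference between dose effects, the fits without 2 libraries and the splits of the samples were chosen only after results were seen. The dose effects of Citri and Cimicifugae differed in 3 of the 9 genes fixed in advance. TXNIP rose more from low to high dose in Citri, by 2.55 ± 0.14 on the log2 scale (edgeR p adjusted over 9 genes after BH = 8.49e-20, n = 3 in each of 4 groups). For HMOX1 the difference was -1.83 ± 0.17 (edgeR, adjusted p = 1.96e-12 over 9 genes). For CYP1A1 it was -1.20 ± 0.39 (edgeR, adjusted p = 0.0118 over 9 genes and 1 over all genes). Over all genes 4 passed in edgeR, 174 without the 2 divergent libraries, and 406 had an unadjusted p under 0.05.

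Replicate 1 of high-dose Aconiti stood apart from its replicates. A GC bias may account for it, since its log2 ratio to its group mates had a Spearman correlation of 0.83 with GC content (52 other libraries -0.33 to 0.33). Group mates of both divergent libraries, whose ratios mirror them, were left out of this range, although the tests as written named 56 libraries. Transcript length gave -0.16 (others -0.36 to 0.26), but medians fell to -0.65 at greatest length, so a length bias stays open. Replicate 1 minus vehicle correlated at 0.09 with the dose effect in replicates 2 and 3, but its GC trend could hide a stronger response. RNA of other cells was not tested.

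Replicate 1 of low-dose Yijung-tang stood apart in another way. Its log2 ratio correlated at -0.45 with transcript length, outside the range of others, so a length bias may be part of it. GC content gave 0.22, inside the range, but medians rose from -0.40 at lowest to 0.55 at highest GC, so a GC bias stays open. Antisense genes had a median log2 ratio of 0.39 (others -0.03 to 0.07), but a loss of strand in this library cannot be told apart from other causes, since lincRNA genes rose alike and the use of strand in counting is not given. No biological explanation was tested for this library.

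All low doses differed from the vehicle once the 2 divergent libraries were left out, with a median of 2826 genes in edgeR. Lower depth of the vehicle and GC trends were argued against as the whole cause, since 87.3% of the median remained after thinning to 15996140 counts, and 73.9% remained after removing GC trends, which lowered Bupleuri from 4740 to 2910 genes, Aconiti from 3545 to 2088 and Yijung-tang from 499 to 301 (also 301 after thinning) and raised Coptidis from 1308 to 1437. A shared dose-dependent effect stays open, as low-dose and dose effects of other sets correlated at 0.032 (median), but dose effects mutually at only 0.069. Low doses of different sets differed from each other by a median of 26.5 genes (0 to 1571 over 18 pairs), and those of one set by 5. A difference between the vehicle and the extract sets in handling, DMSO content or library making cannot be told apart from an effect that all extracts share, since no set holds both.

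For comparisons of 3 with 3 libraries, the other divisions of the same 6 libraries into groups of 3 were counted. The 10 splits are too few for a share under 0.05, so the real count and the highest of the others are given. Against the vehicle these were 5797 and 0, 3316 and 0 and 3127 and 0 for high, medium and low doses of Citri, 6547 and 0, 5066 and 0 and 3083 and 4 for Cimicifugae and 7430 and 0, 4833 and 0 and 2161 and 0 for Bupleuri. Aconiti gave 5120 and 0 at the medium and 4481 and 0 at the low dose. Between high and low doses they were 2223 and 1 for Citri, 1281 and 1 for Cimicifugae and 5162 and 0 for Bupleuri, and 1145 and 3 for Citri against Cimicifugae. In each of these 1 of 10 splits, the real one, reached the real count. High-dose Aconiti gave 0 genes against the vehicle and 0 against its low dose in the real split and in all 10 (edgeR on the 6 libraries, with 1402 and 493 genes at an unadjusted p under 0.05, and 6029 and 2271 called by DESeq2 with all libraries).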

How the results depend on the processing

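Leaving out the 2 divergent libraries, thinning, GC removal and list medians under other scalings were chosen only after results were seen, and the other alternatives before. Of 466 values of named genes, 310 were called, and 207 of these kept direction and call in every alternative while 103 lost the call in at least 1. RLE factors kept all 29 counts within 1.5 times the main count. No scaling moved the median of all genes by over 0.1. The share of higher genes moved by over 10 percentage points in these comparisons with the vehicle, given as higher and lower genes: low-dose Coptidis 6 and 2 in the main analysis, 10 and 7 with DESeq2, low-dose Zizyphi 9 and 3 in the main analysis, 29 and 20 with DESeq2, low-dose Citri 13 and 5 in the main analysis, 43 and 27 with DESeq2, low-dose Bupleuri 29 and 4 in the main analysis, 24 and 7 with RLE factors, 56 and 33 with DESeq2 and medium-dose Aconiti 61 and 11 in the main analysis, 123 and 48 with DESeq2. Of 364 list tests 173 were called, 137 with an estimated correlation, 212 without the 2 libraries and 168 with both changes. The spread shared by all 57 libraries, and with it the 2 divergent libraries, limits the counts, because most comparisons gave more genes without them. The cause of the other changes below was not tested.

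With no filter on low counts the counts that moved became, against the vehicle: Coptidis medium 313, Zizyphi high 110, Citri high 377, medium 28 and low 11, Cimicifugae high 638, medium 323 and low 46, Bupleuri medium 28, Aconiti low 27, Yijung-tang high 362. High against low dose it gave Zizyphi 9, Citri 67, Cimicifugae 45 and Aconiti 476, and Citri against Cimicifugae 24. With DESeq2 they became, against the vehicle: Coptidis low 17, Zizyphi high 438, medium 68 and low 49, Citri medium 166 and low 70, Cimicifugae low 248, Bupleuri medium 87 and low 89, Aconiti medium 171 and low 98, Yijung-tang medium 56. High against low dose it gave Zizyphi 65, Citri 299 and Cimicifugae 189, and Citri against Cimicifugae 101. Without the 2 divergent libraries they became, against the vehicle: Coptidis medium 4560 and low 1308, Zizyphi high 3785, medium 2431 and low 2082, Citri high 5526, medium 3145 and low 2826, Cimicifugae high 6317, medium 5594 and low 3661, Bupleuri high 6987, medium 4004 and low 4740, Aconiti medium 4630 and low 3545, Yijung-tang high 5421, medium 2703 and low 499. High against low dose it gave Coptidis 11678, Zizyphi 1287, Citri 2408, Cimicifugae 1843, Bupleuri 6936 and Yijung-tang 1191, and Citri against Cimicifugae 1193. With only the groups compared they became, against the vehicle: Coptidis medium 5123 and low 2118, Zizyphi high 3410, medium 2317 and low 2596, Citri high 5797, medium 3316 and low 3127, Cimicifugae high 6547, medium 5066 and low 3083, Bupleuri high 7430, medium 4833 and low 2161, Aconiti high 0, medium 5120 and low 4481, Yijung-tang high 5915, medium 3028 and low 0. High against low dose it gave Zizyphi 373, Citri 2223, Cimicifugae 1281, Bupleuri 5162, Aconiti 0 and Yijung-tang 0, and Citri against Cimicifugae 1145. The counts of 0 are from edgeR, where 1402 genes of high-dose Aconiti, 787 of low-dose Yijung-tang, 493 between the doses of Aconiti and 125 between those of Yijung-tang had an unadjusted p under 0.05, and DESeq2 with all libraries called 6029, 5980, 2271 and 4658.

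Leaving out 1 library at a time, with a lone remaining library assumed to vary like the other groups, gave these ranges at high, medium and low dose: Coptidis 6337 to 7615, 261 to 424 and 3 to 7, Zizyphi 52 to 154, 1 to 18 and 0 to 11, Citri 400 to 558, 20 to 34 and 3 to 18, Cimicifugae 683 to 848, 315 to 539 and 46 to 101, Bupleuri 1798 to 1949, 3 to 19 and 10 to 26, Aconiti 1885 to 8550, 14 to 51 and 12 to 17, Yijung-tang 234 to 500, 0 to 8 and 4 to 11114. High against low dose gave Coptidis 5881 to 6191, Zizyphi 3 to 8, Citri 52 to 106, Cimicifugae 52 to 62, Bupleuri 1779 to 1964, Aconiti 547 to 6298 and Yijung-tang 185 to 10555, and Citri against Cimicifugae 25 to 36.

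Values that changed sign without the 2 divergent libraries were DDIT3 in low-dose Yijung-tang against vehicle (-0.093), and DDIT3 (0.97) and MKI67 (-0.56) in high-dose against low-dose Yijung-tang. Without only replicate 1 of low-dose Yijung-tang the 2 values of DDIT3 were -0.083 and 0.97, and without only replicate 2 the value between doses was -0.58. Without the 2 libraries, lists that turned were the epithelial markers in high-dose Aconiti (camera adjusted p = 0.00283 against vehicle and 0.000412 against low dose) and the neuron markers between doses of Yijung-tang (camera adjusted p = 0.0262). The median of the neuron list, high against low dose in Citri, became 0.024 with DESeq2, which was run without the low-count filter.

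Replicate numbers were not shown to pair samples. The deviations of libraries with the same number and set had a median correlation of 0.012 over 107 pairs, and in 0 of 29 comparisons were all pairs above 0.1. With a replicate block all 29 counts stayed within 1.5 times, for example 8245 genes for high-dose Coptidis, and 172 list tests were called. The block within the set kept all 8 counts it was run on. The edgeR adjusted p moved to 0.0547 for MT-ND1 in high-dose Citri, 0.0549 for CLTRN in high-dose Yijung-tang, 0.0603 for ACTC1 between doses of Zizyphi, 0.0538 and 0.0445 for DDIT3 and HMGCS1 between doses of Aconiti and 0.0597 for KRTAP1-5 between Citri and Cimicifugae. The camera adjusted p moved to 0.0524 for the cholesterol list in high-dose Bupleuri, 0.0571 for the microglia and leukocyte markers between doses of Bupleuri and 0.0487 for the astrocyte markers between doses of Coptidis. The block changed no other call.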

Other observations

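The tests on mitochondrial ribosomal RNA, on Banhasasim-tang, on the response to sugar and on genes moving in all extracts were chosen only after results were seen. Mitochondrial ribosomal RNA took a larger share of counts than in the vehicle after Coptidis and, less so, after the low doses of all other replicated extracts. MT-RNR2 held 0.846% of counts in the vehicle, 1.79% at the low, 8.45% at the medium and 3.29% at the high dose of Coptidis (n = 3, 2, 2 and 2). It passed at the medium and high dose (largest edgeR adjusted p = 2.21e-08) but not at the low dose (0.251, or 6e-18 without the 2 divergent libraries). At the low doses of the other extracts it did not pass with all libraries (lowest edgeR adjusted p = 0.277, in Yijung-tang). Without the 2 divergent libraries it lay 0.37 (Bupleuri) to 0.51 (Zizyphi) above the vehicle there, on the log2 scale. MT-RNR1 rose by 4.97 ± 0.22 at the medium dose, 4.06 ± 0.22 at the high and 1.70 ± 0.20 at the low dose (largest edgeR adjusted p = 4.43e-06). Banhasasim-tang libraries held 3.35%, 7.96% and 6.09% MT-RNR2 from low to high dose, with 1 library each. Whether RNA selection or the cells changed was not tested.

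Without the 2 divergent libraries, some genes rose and others fell with dose in all 7 extracts. Low-dose Yijung-tang then had 1 library, its spread taken from other groups. Chance overlap is unknown, since the tests share each gene's spread. Solvent was not tested. The rises included the stress-responsive NDRG1 (log2 0.32 to 3.30 over the extracts), the NAD synthesis enzyme NAMPT (0.26 to 1.43), the lipid droplet coat PLIN2 (0.19 to 2.31), the NRF2 target SRXN1 (0.12 to 0.50) and the death receptor TNFRSF10B (0.19 to 2.47). Falls included the collagens COL1A2 (-1.62 to -0.21) and COL3A1 (-1.35 to -0.26), caveolin CAV1 (-0.86 to -0.20), KRT18 (-2.03 to -0.19), the chemokine CXCL12 (-1.93 to -0.42) and LGR6 (-3.81 to -0.59). At the low dose, in comparisons that share the 3 vehicle libraries and so their chance deviations, with no value simulated without effects, 101 genes were higher and 183 lower than in the vehicle in all 7 extracts, with means of 1.24 for SLX1A, 0.98 for EGR1, -0.70 for SAMD4A and -0.55 for HAS2.

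Banhasasim-tang may act in part through Coptidis Rhizoma, one of its ingredients. Over genes with a mean of at least 10 CPM, its high-dose difference from the vehicle had a Pearson correlation of 0.75 with the dose effect of Coptidis, which shares no library with it, and 0.09 with that of Zizyphi, another ingredient. The other extracts ran from -0.12 for Yijung-tang to 0.37 for Aconiti, but Yijung-tang reached 0.61 without the 2 divergent libraries, so a stress response common to several extracts stays open.

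Sugar carried by the extracts into a medium without glucose could raise TXNIP, and would then also lower ER chaperones. From low to high dose the ER chaperone list had a median of -0.18 in Zizyphi (0 of 14 genes passed, camera adjusted p = 0.00179), which is in line with this, and 6 fell without the 2 divergent libraries. In Citri it was -0.077 (0 passed, camera adjusted p = 0.158, and 0.00142 without the 2 divergent libraries). In Cimicifugae it was 0.16 (1 rose, camera adjusted p = 8.87e-07), opposite to this, but other effects could mask a fall. The list was also low in Bupleuri, where TXNIP fell (2 fell, median -0.22, camera adjusted p = 0.0747, and 0.00239 without the 2 libraries), so it is not specific to sugar.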
